A study of Mus musculus with 107 samples.

How the data were processed

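RNA from 24 TRAP populations and from the unbound fraction of 6 tissues was measured on Affymetrix arrays with 45101 probe sets. Per the labels, the authors amplified the RNA in an Affymetrix procedure with 2 cycles, labelled it with biotin and computed GCRMA values, with the replicates of a group normalized together. The GCRMA version is not given. The deposited values are intensities on a linear scale. Their lowest value is shared by sets of arrays, and 30 such sets, the largest of 9 arrays, show which arrays were normalized together. The series text names the replicates as independent TRAP preparations and recommends a further scaling between groups on the Affymetrix biotinylated controls and a filter on the ratio of TRAP to unbound RNA. Both were applied here. Unbound RNA of one tissue was pooled over the lines it came from, with corpus striatum taken as striatum. GCRMA sets many weak signals to its minimum: 25.8% to 41.6% of the values of an array. In groups of 3 arrays 1.34% to 19.2% of values were identical in all replicates, also in strong genes (Eya1, 14.31 in Drd1 TRAP). This narrows their spread.

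Intensities were floored at 1 and turned into log2 values. Each group was then shifted by 1 constant so that the mean of 18 biotinylated control probe sets was equal in all groups, since their mean log2 intensity ran from 10.13 to 12.66. Of the probe sets, 34945 carry exactly 1 gene symbol, 932 carry several and 9224 carry none. A gene was represented by its probe set with the highest mean, which gave 18193 genes, 9010 of them with several probe sets. Genes needed a group mean of at least 6 (an intensity of 64) in 1 of the groups compared. Linear models were fitted with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8): 1 fit over all arrays with 1 coefficient per TRAP population and 1 per tissue for unbound RNA, followed by eBayes with trend = TRUE. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05 and a change of at least 2-fold. The 17 comparisons of populations also required the gene to be higher in TRAP than in unbound RNA in a compared population and, for a call, on the higher side. Where several populations form a side, their means were averaged and the SD is the pooled SD within populations. A fold is a lower bound where a population of the lower side lies under the minimum of 6, with that population set to 6 before averaging. P-values measure the spread of replicate preparations within the groups of the whole fit, and for unbound RNA also that between the lines pooled in a tissue. They do not measure the spread between populations averaged on a side.

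The gene lists (cell-type markers for astrocytes, Bergmann glia, oligodendroglia, microglia, vessels, choroid plexus and the neuron classes, and gene families) and the comparisons, tests and most alternatives were chosen before the data were examined. The lists were tested with limma's camera with a correlation estimated from the data, against all genes tested in the comparison, where at least 3 members were tested, and adjusted over the lists of that comparison. A preset correlation of 0.01 was an alternative. Members were also counted when adjusted over the list alone. Genes named in a comparison are the drivers, members of its lists and the 8 genes with the largest called difference in each direction whose arrays do not overlap between the sides. Chance gives that separation in 10% of the genes with 3 against 3 arrays. For TRAP against unbound RNA they are the driver and the 3 genes at the top. Members of lists of other cell types, named beside a group, were taken as examples after their values were seen. Similarity between populations is Pearson's r across 12600 genes, and clusters come from the same correlations.

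The model was tested on arrays simulated gene by gene with the fitted spread, with 100 genes changed per size. For Drd1 against Drd2, 86% of changes of 1.5 log2 units and 100% of changes of 3 were called. False calls were 3 of 9325 genes (7450 in real data). For Purkinje neurons 98% and 100% were called with 1 false call among 8333 genes, and for Drd1 TRAP against unbound RNA 95% and 100% with 6 false calls among 9387. Camera detected both raised lists and neither unchanged one. Real list genes correlate and gene numbers differ, so these results may not carry over.

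Alternatives were no further scaling, quantile normalization over all arrays, no expression filter or a minimum of 8, the mean of all probe sets of a gene, limma's treat with a 2-fold bound, eBayes without trend, fits on the compared arrays alone, no requirement of TRAP over unbound RNA or one of 1.5-fold, differences of TRAP minus unbound RNA between tissues, the unbound arrays of the same line alone, single BAC lines where a population had several, the replicate number as a block, and leaving out each replicate in turn. After the data were seen, 4 more were added: genes called under both scalings, scaling by set of arrays normalized together, the Cort+ comparison without layer 5a, and the cerebellar comparisons without Golgi neurons. Counts called under both scalings are therefore given beside those with control-probe scaling. Whether numbers in the sample names pair the arrays was tested on the residuals: of 23 pairs of TRAP and unbound arrays with the same line and number 13 correlated above 0.1 (median 0.11, from −0.26 to 0.58), and of 117 pairs with the same number across compared populations 23 did. All 3 pairs of brainstem motor neurons (0.46 to 0.58) and of basal forebrain cholinergic neurons (0.29 to 0.46) correlated, so there the numbers pair the arrays. The reported values use no block even there, since elsewhere lines were pooled or most pairs did not correlate. With the block, 974 genes in place of 934 were higher in TRAP RNA in brainstem and 820 in place of 807 in basal forebrain. Raw array images were not used here, and probe sets without a symbol entered only as a count.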

Results

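The series measured the mRNA carried by ribosomes in 24 defined cell populations of the mouse central nervous system. It used translating ribosome affinity purification (TRAP), in which a bacterial artificial chromosome (BAC) transgene places a tagged ribosomal protein under the regulatory region of a cell-type gene, here called the driver, so that ribosomes of the labelled cells can be pulled out of whole tissue. RNA that stayed behind after the purification (unbound RNA) stands for the tissue as a whole. Affymetrix arrays were hybridized. Each population had 3 TRAP arrays, apart from cortical astrocytes with 4 and Purkinje neurons with 6. The unbound arrays numbered 9 for cortex, 7 for cerebellum, 6 for striatum and 3 each for basal forebrain, brainstem and spinal cord. Cortical neurons made 6 populations, those of layers 5a, 5b and 6 and the Cort+, Cck+ and Pnoc+ neurons. Medium spiny neurons came from a Drd1 and a Drd2 line, and cholinergic neurons from striatum, basal forebrain, brainstem and spinal cord. The cerebellum gave Purkinje, granule, Golgi, unipolar brush and stellate and basket neurons. The 7 glial populations were astrocytes, mature oligodendrocytes and mixed oligodendroglia, each from cortex and cerebellum, and Bergmann glia. Values are log2 intensities after scaling on control probe sets, given as mean ± SD, or without an SD where the replicates were identical. A gene was called where its adjusted p lay under 0.05 and its change reached 2-fold. In a comparison of populations the gene also had to be higher in TRAP than in unbound RNA on the higher side. Where a population on the lower side lay under the expression minimum of 6, it was set to 6 and the fold is a lower bound. Each adjusted p of a gene list was computed with an estimated correlation between its genes, and is also given under quantile normalization where that moved it across 0.05. The number of arrays limits the precision.

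The first question was whether each population carried the gene that drove its tag. Of 19 driver tests, 17 were called higher in TRAP than in unbound RNA. The neuropeptide gene Grp, driver of the unipolar brush line, stood at 14.89 ± 0.06 (n = 3) against 4.43 ± 0.26 in 7 unbound arrays, at least 474-fold higher. The transcription factor Olig2 stood at 12.11 ± 0.08 in cerebellar mixed oligodendroglia against 4.27 ± 0.44 (at least 68.8-fold) and at 12.16 ± 0.36 in the cortical ones against 6.72 ± 0.57 (43.4-fold). Cmtm5, driver of the mature oligodendrocyte line, was 40.7-fold higher in cortex (12.21 ± 0.08 against 6.86 ± 0.82) and 6.70-fold higher in cerebellum (12.54 ± 0.63 against 9.79 ± 0.40). Aldh1l1, a folate enzyme of astrocytes, was 18.8-fold higher in cortical astrocytes (11.65 ± 0.30, n = 4, against 7.42 ± 0.88) and 5.68-fold higher in the cerebellar ones (10.08 ± 0.02 against 7.57 ± 0.59). Among the cortical neurons, the neuropeptide genes Pnoc (10.19 ± 0.15, at least 18.3-fold) and Cort (9.17 ± 0.19, at least 9.0-fold) were higher, with unbound values under the minimum. The same held for Colgalt2 of layer 5b (9.89 ± 0.49, at least 14.8-fold) and the neurotensin receptor Ntsr1 of layer 6 (9.45 ± 0.28, at least 10.9-fold). In the cerebellum, Grm2 of Golgi neurons (10.36 ± 0.02 against 6.79 ± 0.11, 11.9-fold) and Lypd6 of stellate and basket neurons (13.97 ± 0.03 against 10.62 ± 0.35, 10.2-fold) were higher. So were Septin4 of Bergmann glia (15.87 ± 0.17 against 13.53 ± 0.37, 5.03-fold) and Pcp2 of Purkinje neurons (16.12 ± 0.17, n = 6, against 14.74 ± 0.49, 2.60-fold). The dopamine receptor genes were higher in their own lines, Drd2 9.99-fold (14.16 ± 0.36 against 10.83 ± 0.88) and Drd1 2.12-fold (14.00 ± 0.19 against 12.92 ± 0.41). The Drd1 call ended under quantile normalization, and without scaling the difference turned to −0.18. Cck (13.60 ± 0.28 against 13.05 ± 0.64, adjusted p = 0.39) and Neurod1 of granule neurons (14.80 ± 0.12 against 14.39 ± 0.23, adjusted p = 0.39) were not called. Chat, which encodes the enzyme that makes acetylcholine, stood at 2.15 to 2.74 in the 4 cholinergic populations, near the lowest value of the arrays, and under the expression minimum it was not tested there. Slc18a3, the vesicular acetylcholine transporter, gained most of all genes in 3 of the 4. The driver of the layer 5a line is not analysed here.

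**Figure D1:**
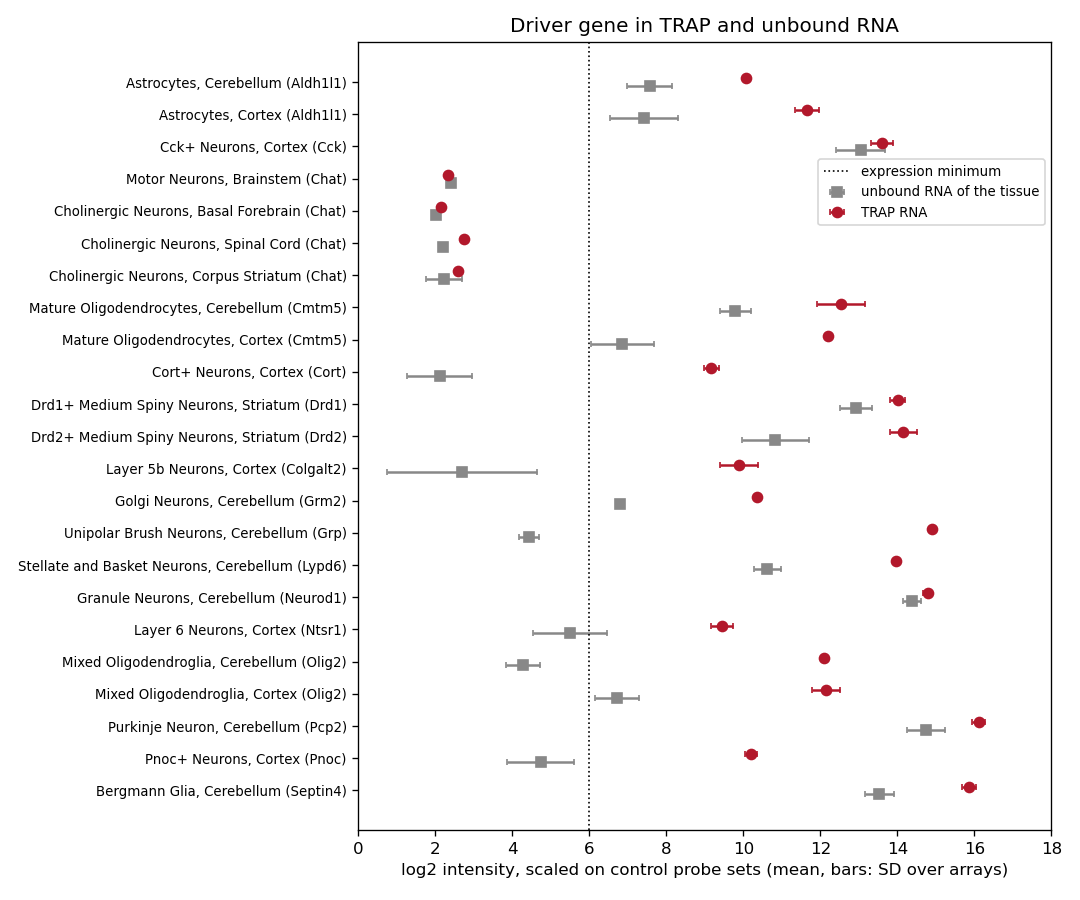
Log2 intensity of the driver gene of each population (x axis, mean, bars give the SD over arrays) in TRAP RNA (red circles) and in unbound RNA of its tissue (grey squares), with the expression minimum of 6 as a dotted line. The widest gap is Grp in unipolar brush neurons, 14.89 ± 0.06 against 4.43 ± 0.26, and Chat lies under the minimum in all 4 cholinergic populations.

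Beyond the drivers, the leading genes often named the cell type. Whether a BAC carried any was not tested. Slc18a3 stood at 13.14 ± 0.06 in striatal (at least 141-fold), 11.86 ± 0.13 in basal forebrain (at least 58.1-fold) and 13.45 ± 0.26 in brainstem cholinergic neurons (131-fold, n = 3 each). Mnx1, a homeobox gene of motor neurons, was among the leading genes in spinal cord (7.87 ± 0.03). Cortical astrocytes were led by Tst, Cmtm3 and Lcat, a cholesterol-esterifying enzyme (11.73 ± 0.82, at least 52.9-fold). Mature oligodendrocytes shared Ninj2 (10.54 ± 0.32 in cortex, at least 23.3-fold, and 11.04 ± 0.74 in cerebellum, at least 32.9-fold). Pnoc+ neurons held the serotonin receptor Htr3a (9.32 ± 0.08, at least 9.97-fold) and the neuropeptide gene Tac2 (11.43 ± 0.08, at least 43.2-fold), and unipolar brush neurons the calcium-pump regulator Sln (14.94 ± 0.04, 369-fold). Bergmann glia were led by the Wnt inhibitor Wif1 (11.58 ± 0.74, at least 47.8-fold), and cerebellar mixed oligodendroglia by Meox1 (12.20 ± 0.29, at least 73.3-fold). In some populations the leading genes belong to other cells or recur across unrelated cells. In layer 5a these were Cbr2 (11.62 ± 0.96, at least 49.2-fold), the mannose receptor Mrc1 (10.71 ± 0.92, at least 26.1-fold) and Clec10a, genes of macrophages, and layer 5b held Sox18, an endothelial transcription factor (8.47 ± 0.79, at least 5.54-fold). The nuclease gene Samhd1 (13.54 ± 0.10 in Cck+, 13.63 ± 0.07 in Cort+ and 13.15 ± 0.17 in granule neurons) and Cacng7 were leaders in neurons of both cortex and cerebellum. Per population, a median of 1485.5 genes were called higher in TRAP RNA, from 272 to 6396. The median of all expressed genes shifted by −1.96 to 1.31 between the fractions, and a median of 1380 genes were called higher under both this scaling and quantile normalization.

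Lists of cell-type genes fixed beforehand were tested in each population. Relative to the median of all genes tested, the astrocyte list stood 3.63 log2 units above unbound RNA in cortical astrocytes (18 of 18 genes higher, adjusted p = 0.27) and the myelinating oligodendrocyte list 4.19 in cortical mature oligodendrocytes (16 of 16, adjusted p = 0.26). The oligodendrocyte progenitor list stood at 5.16 in cerebellar mixed oligodendroglia (9 of 10, adjusted p = 0.067 and 0.0013 under quantile normalization) and the motor neuron list at 5.63 in brainstem motor neurons (7 of 7, adjusted p = 0.012). The cholinergic list stood at 7.19 in basal forebrain (3 of 3, adjusted p = 0.021) and the Golgi neuron list at 4.17 in Golgi neurons (6 of 7, adjusted p = 0.046 and 0.16 under quantile normalization). In Purkinje neurons 9 of 10 genes of their list were higher (2.63, adjusted p = 0.65), and in Pnoc+ neurons 9 of 16 cortical interneuron genes (3.20, adjusted p = 0.055 and 0.036 under quantile normalization). Genes of other cells were higher too. In layer 5a, 9 of 9 microglia genes were (1.80, adjusted p = 0.95), as were 6396 of all 10556. In layer 5b, 9 of 11 vascular genes were (2.45, adjusted p = 0.98 and 0.049 under quantile normalization). Of 11 pan-neuronal genes, 11 were lower in cortical astrocyte TRAP than in unbound RNA (−4.69, adjusted p = 0.27), and of 18 astrocyte genes 17 were lower in Purkinje neurons (−4.71, adjusted p = 0.65). Across the 12600 genes expressed in any population, the pairs of populations with the most similar mean levels were the Drd1 and Drd2 medium spiny neurons (r = 0.983 across genes, which are not independent replicates). Next came basal forebrain and striatal cholinergic neurons (0.975), layer 5b and layer 6 neurons (0.965) and brainstem and spinal cord cholinergic neurons (0.957). Divided into 2 clusters, the 7 glial populations separated from the neurons. Arrays of one group correlated at 0.966 to 0.999.

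**Figure D2:**
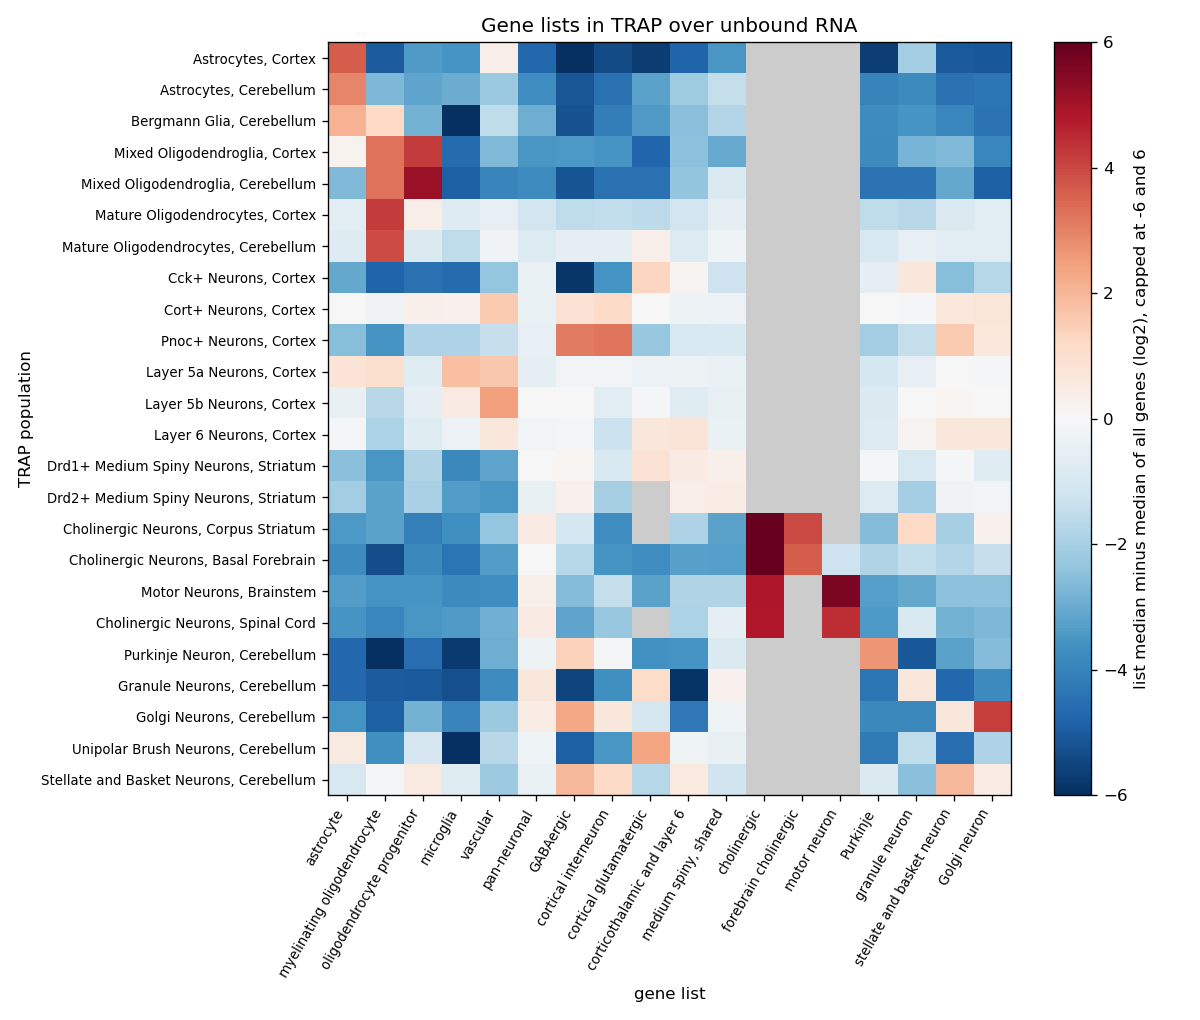
Median log2 difference between TRAP and unbound RNA of cell-type lists (columns) in each population (rows), relative to the median of all genes tested there, with red for higher and blue for lower. The astrocyte list reaches 3.63 in cortical astrocytes and the myelinating oligodendrocyte list 4.19 in cortical mature oligodendrocytes.

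Medium spiny neurons project from the striatum along the direct pathway (Drd1 line) or the indirect pathway (Drd2 line), and the question was how the translated mRNA of these neighbours differs. Genes known for the direct pathway were higher in the Drd1 line: Drd1 itself (14.00 ± 0.19 against 11.91 ± 0.35, 4.26-fold, n = 3 each) and the neuropeptide genes Tac1 (14.93 ± 0.12 against 12.33 ± 0.07, 6.08-fold) and Pdyn (9.86 ± 0.19 against 6.64 ± 0.10, 9.33-fold). The transcription factors Eya1 (14.31 against 9.01 ± 0.46, 39.5-fold) and Isl1 (10.8-fold) were higher there too. Higher in the Drd2 line were Drd2 (9.20 ± 0.26 against 14.16 ± 0.36, 31.0-fold), the enkephalin precursor Penk (12.09 ± 0.24 against 14.63 ± 0.26, 5.84-fold) and the orphan receptor gene Gpr6 (11.10 against 14.43 ± 0.15). So were Nt5e, which makes adenosine (8.62-fold), and Ttc12 (3.61 against 13.59 ± 0.17, at least 193-fold), which lies beside Drd2, perhaps on its BAC. All 8 tested genes of the Drd1 list were higher in the Drd1 line (median difference 3.19, adjusted p = 2.6e-07), and all 4 of the Drd2 list in the Drd2 line (median difference −2.93, adjusted p = 2.3e-11). Counts adjusted over the list alone were also 8 and 4. Of 9 genes known in all medium spiny neurons none was called by limma and 0 had an unadjusted p under 0.05, among them Ppp1r1b (13.97 ± 0.25 against 13.89 ± 0.37) and Pde10a (14.72 ± 0.03 against 14.39 ± 0.07). Their median difference 0.20, adjusted p = 0.99, tested against a median of 0.37 over all genes and so with a negative sign. Genes of cortical projection neurons were higher in the Drd1 line as well: 3 of 5 tested genes of the cortical glutamatergic list (median difference 2.66, adjusted p = 0.10 and 0.017 under quantile normalization), such as Tbr1 (9.38 against 4.53) and Neurod6 (8.38 ± 0.74 against 3.20 ± 0.04). Of 12 genes of the layer 6 list 8 were higher (median difference 1.73, adjusted p = 0.16 and 0.0062 under quantile normalization), such as Cplx3 (8.16 ± 0.14 against 3.24), with Grik3 lower (9.84 ± 0.18 against 11.51 ± 0.01). Under both scalings 170 genes were higher in the Drd1 and 62 in the Drd2 line. Control-probe scaling alone gave 527 and 65 of 7450 tested, with a median shift of 0.35, and quantile normalization 170 and 122.

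**Figure D3:**
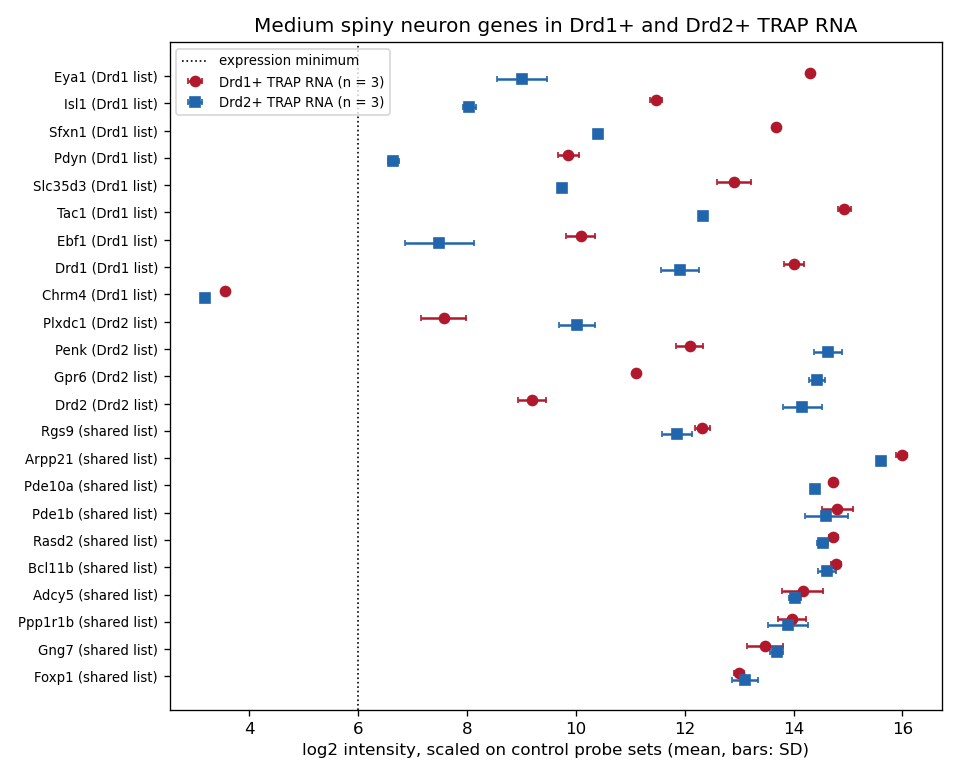
Log2 intensity of the genes of the Drd1, Drd2 and shared medium spiny lists in the 3 Drd1 and 3 Drd2 TRAP arrays (means and SD). Drd2 stands at 9.20 ± 0.26 in the Drd1 and 14.16 ± 0.36 in the Drd2 line.

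Layer 5a and layer 5b hold cortical neurons with different targets, within the hemispheres and below the cortex. Set against layer 5b, the largest gains of layer 5a TRAP RNA included genes of macrophages: the chemokine gene Pf4 (11.91 ± 0.56 against 3.22 ± 0.09, at least 59.9-fold, n = 3 each) and Cbr2 (11.62 ± 0.96 against 3.14 ± 0.39, at least 49.2-fold), followed by the lysozyme genes Lyz1 (14.35 ± 0.56 against 6.83 ± 0.35, 184-fold) and Lyz2 (11.95 ± 0.76, at least 61.7-fold). Layer 5b was higher for its driver Colgalt2 (4.83 ± 0.12 against 9.89 ± 0.49, at least 14.8-fold). It was also higher for genes of blood vessels, the endothelial factor Sox17 (8.85 ± 0.64, at least 7.20-fold), the growth factor receptor Flt1 (at least 3.10-fold, difference −5.82 to −4.83 when 1 array is left out) and the transporter Slco1a4 (at least 6.91-fold). Of 11 tested callosal genes 1 was higher, the growth inhibitor Btg1 (11.23 ± 0.18 against 10.12 ± 0.80), and 1 lower, Inhba (6.49 ± 0.25 against 7.70 ± 1.08, 2.32-fold), with 9 not called. Their median difference 0.58, adjusted p = 0.93, lay beside a median of 0.60 over all genes, so the test ran in the negative direction. Of 12 subcerebral genes 1 was lower, Colgalt2, and 11 were not called (median difference −0.37, adjusted p = 0.31 and 0.0040 under quantile normalization), among them Bcl11b, a regulator of corticospinal neurons (11.71 ± 0.17 against 12.65 ± 0.28). Under quantile normalization 4 were lower. The counts adjusted over the list alone were the same. Genes of other cells moved along: 7 of 9 microglia genes were higher in layer 5a (median difference 4.23, adjusted p = 0.31). So were 15 of 15 myelinating oligodendrocyte genes (median difference 2.45, adjusted p = 0.42) and 15 of 18 astrocyte genes (median difference 1.74, adjusted p = 0.93), while of 11 vascular genes 5 were lower and 3 higher (median difference −0.91, adjusted p = 0.31). Genes called under both scalings numbered 818 higher and 71 lower, against 2650 and 151 of 9701 with control-probe scaling, where all genes shifted by 0.55, and 818 and 364 with quantile normalization. The Btg1 call ended without layer 5b replicate 1 (0.91) or replicate 2 (0.85), and Btg1 and Inhba were not tested under quantile normalization.

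Layer 6 neurons send axons to the thalamus, and the comparison with layer 5b asked which genes part the deep layers. Layer 6 was higher for its driver Ntsr1 (6.37 against 9.45 ± 0.28, 8.44-fold, n = 3 each) and for Foxp2, a transcription factor of corticothalamic neurons (7.24 ± 0.27 against 10.08 ± 0.39, 7.14-fold). The corepressor Tle4 (10.60 ± 0.15 against 12.19 ± 0.21, 3.01-fold) and the complexin Cplx3 (6.36 ± 0.23 against 8.61 ± 0.36, 4.75-fold) were higher there too. Layer 5b was higher for Colgalt2 (9.89 ± 0.49 against 2.75, at least 14.8-fold), its largest difference, and the cadherin Cdh22 (10.05 ± 0.24 against 8.94 ± 0.04, 2.16-fold). Endothelial genes were also among its largest differences, such as Sox17 (8.85 ± 0.64 against 2.79 ± 1.06, at least 7.20-fold, difference 5.75 to 6.67 when 1 array is left out) and the tight-junction gene Cldn5 (9.46 ± 0.42 against 3.82, at least 11.0-fold). Of 13 tested genes of the corticothalamic and layer 6 list 8 were higher in layer 6 and 5 not called, 10 when adjusted over the list alone (median difference −1.59, adjusted p = 0.10 and 3.0e-05 under quantile normalization). Of 12 subcerebral genes 3 were higher in layer 5b and 9 not called (median difference 0.54, adjusted p = 0.98), the third being Ldb2 (12.37 ± 0.03 against 11.33 ± 0.44), whose call ended without layer 6 replicate 3 (0.84). Of 11 vascular genes 7 were higher in layer 5b and 1, Pdgfrb of pericytes, lower (median difference 2.11, adjusted p = 0.10 and 0.0010 under quantile normalization). Under both scalings 538 genes were higher in layer 5b and 318 in layer 6. Control-probe scaling gave 869 and 436 of 8719, with a shift of 0.08. Quantile normalization gave 566 and 513.

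Cort+ neurons, cortical interneurons marked by the neuropeptide cortistatin, were set against the mean of layers 5a, 5b and 6 to find interneuron genes. Higher were Cort (9.17 ± 0.19 against 2.18, n = 3 against 9) and the neuropeptide genes Sst (13.78 ± 0.16 against 8.97 ± 0.80, 27.9-fold) and Npy (13.79 ± 0.11 against 9.58 ± 0.80, 18.5-fold). The calcium buffer Pvalb (12.97 ± 0.24 against 10.47 ± 0.45, 5.66-fold) and the interneuron transcription factor Lhx6 (9.54 ± 0.37 against 7.41 ± 0.32, 4.38-fold) were higher as well. Lower were Slc17a7, the vesicular glutamate transporter of cortical projection neurons (8.57 ± 0.37 against 10.64 ± 0.62, 4.20-fold), the cortical factor Emx1 (4.82 ± 0.20 against 7.12 ± 0.18, at least 2.18-fold) and the interneuron gene Reln (11.29 ± 0.01 against 12.81 ± 0.30, 2.85-fold). The largest gains were Samhd1 (13.63 ± 0.07 against 3.95 ± 0.94, at least 174-fold), Tcl1b3 (11.54 ± 0.33, at least 46.5-fold) and Cacng7 (11.22 ± 0.29 against 3.62 ± 0.0025, at least 37.2-fold), which are not known as interneuron genes. Of 16 cortical interneuron genes 7 were higher, 2 lower and 7 not called (median difference 0.85, adjusted p = 0.93). Of 6 GABAergic genes 3 were higher and 3 not called (median difference 0.69, adjusted p = 0.93), among the latter the GABA-synthesizing enzyme Gad1 (14.57 ± 0.06 against 14.90 ± 0.19). Of 7 cortical glutamatergic genes 2 were lower (median difference −0.79, adjusted p = 1.00). One GABAergic call, Dlx1, ended without Cort+ replicate 1 (0.93). Under both scalings 407 genes were higher and 1370 lower. With control-probe scaling the counts were 472 and 3662 of 10267 with a shift of −0.66, and with quantile normalization 955 and 1370.

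Cholinergic neurons were compared first within the forebrain, striatal interneurons against basal forebrain projection neurons. Striatal neurons were higher for Rgs6, a regulator of G-protein signalling (8.44 ± 0.003 against 2.80 ± 0.36, at least 5.44-fold, n = 3 each), the cation channel Trpc6 (8.14 ± 0.18 against 4.07 ± 0.20, at least 4.40-fold) and Mamdc2 (8.95 ± 0.67, at least 7.71-fold). Leaving out 1 array put the Mamdc2 difference at 3.98 to 5.16. Basal forebrain neurons were higher for the adenylyl cyclase Adcy8 (5.78 against 8.81 ± 0.22, at least 7.01-fold), the sphingosine phosphate receptor S1pr3 (at least 5.43-fold) and the peroxidase Gpx2 (at least 3.04-fold). Regional identity genes of the ventral forebrain were not called, with Lhx8 at 14.42 ± 0.16 against 14.59 ± 0.10 and Zic1 at 14.75 ± 0.30 against 14.96 ± 0.11. When each tissue's unbound RNA was subtracted, Zic1 turned to 1.61 and Zic4 to 2.52. Of 5 forebrain cholinergic genes 0 were called by limma, 1 with an unadjusted p under 0.05 (median difference −0.07, adjusted p = 0.90). Of 3 cholinergic genes 1 was higher (median difference 1.12, adjusted p = 0.90), Slc18a3 (13.14 ± 0.06 against 11.86 ± 0.13, 2.43-fold), a call not made under quantile normalization. Ttr, a choroid plexus gene, stood at 14.77 ± 0.87 against 9.83 ± 1.64, and its call ended without basal forebrain replicate 1 (4.18) or 3 (4.81) or striatal replicate 1 (5.13) or 3 (4.44) and under quantile normalization (4.25). Of 10 genes shared by medium spiny neurons, striatal neighbours of these cells, 9 were not tested because they lay lower in TRAP than in unbound RNA in both regions. Of the 9, 7 were at least 2-fold higher in striatal TRAP RNA without overlap, such as Ppp1r1b (8.14 ± 0.40 against 6.09 ± 0.28) and Rgs9 (7.94 ± 0.16 against 6.16 ± 0.03), and 3 under quantile normalization. Under both scalings 279 genes were higher in striatal and 61 in basal forebrain neurons. Control-probe scaling gave 637 and 61 of 4820, with a shift of 0.29. Quantile normalization gave 324 and 244.

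Brainstem motor neurons and spinal cord cholinergic neurons share their transmitter and lie at different levels of the body axis. Brainstem neurons were higher for the homeobox gene Shox2 (12.03 ± 0.81 against 2.85 ± 0.23, at least 65.3-fold, n = 3 each) and for Tbx20, a factor of cranial motor neurons (8.79 ± 0.20 against 2.69, at least 6.90-fold). The neuropeptide genes Vip (10.49 ± 0.80 against 4.97 ± 0.0018, at least 22.5-fold) and Gal (11.12 ± 1.46 against 6.34 ± 0.33, 27.5-fold) were also higher there. Spinal cord neurons were higher for Hoxc5, a homeobox gene of the body axis (7.22 ± 1.94 against 10.29 ± 0.05, 8.45-fold), the transcript Hoxb5os of another Hox cluster (6.59 ± 0.99 against 9.78 ± 0.16, 9.11-fold) and Sln (2.83 ± 0.10 against 8.04 ± 0.35, at least 4.11-fold). Leaving out 1 array put the Hoxc5 difference at −3.71 to −1.96, the latter without brainstem replicate 1, and that of Gal at 4.28 to 5.62. Posterior Hox genes such as Hoxa9 (2.34 against 12.20 ± 0.10) and Hoxc8 (2.34 against 12.09 ± 0.12) stood high in cord but were not tested, since they were not higher in TRAP than in unbound cord RNA. Of 8 motor neuron genes 1 was higher in brainstem, Isl1 (11.94 ± 0.52 against 10.60 ± 0.19, 2.54-fold), a call not made under quantile normalization. A further 2 were lower and 5 not called (median difference −0.09, adjusted p = 0.52 and 0.0029 under quantile normalization), among the latter the peptide gene Calcb (14.59 ± 0.08 against 14.19 ± 0.27). Both lower ones, Mnx1 (6.03 ± 1.97 against 7.87 ± 0.02) and Isl2 (4.87 ± 0.40 against 6.07), lost their call without brainstem replicate 1 (−0.71 and −0.97). Under quantile normalization 3 were lower and 0 higher. Genes called under both scalings were 363 higher in brainstem and 50 in cord. Control-probe scaling gave 1571 and 50 of 4101, with a shift of 0.77. Quantile normalization gave 536 and 499.

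The hindbrain and cord populations together were set against both forebrain populations, to part motor neurons from other cholinergic neurons. Motor neuron genes were higher in hindbrain and cord: the peptide gene Calcb (14.39 ± 0.20 against 2.37, at least 335-fold, n = 6 each) and the intermediate filament genes Prph (13.20 ± 0.13 against 2.37, at least 147-fold) and Nefh (14.04 ± 0.29 against 8.57 ± 0.14, 44.4-fold). Chodl, a marker of fast motor neurons, was higher as well (13.29 ± 0.11 against 3.48, at least 156-fold). Forebrain neurons were higher for the forebrain transcription factors Lhx8 (2.63 ± 0.0028 against 14.51 ± 0.14, at least 363-fold) and Zic1 (8.10 ± 0.34 against 14.85 ± 0.23, 108-fold). They were also higher for the neurotrophin receptor Ngfr (3.77 against 10.93 ± 0.62, at least 30.4-fold) and the dopamine receptor Drd2 (2.87 against 11.14 ± 0.78, at least 35.3-fold). Of 8 motor neuron genes 7 were higher and 1, Isl1, lower (11.27 ± 0.39 against 12.99 ± 0.12, 3.30-fold; median difference 5.03, adjusted p = 0.029), and all 5 forebrain cholinergic genes were lower (median difference −6.76, adjusted p = 0.029). The Hox list also moved (median difference 3.75, adjusted p = 0.036), though of 14 members only Hoxc5 was called (8.76 ± 1.37 against 2.37, at least 6.75-fold) and 7 were called under quantile normalization. The other 13 passed in limma but were not higher in TRAP than in unbound RNA. Without brainstem replicate 1 Hoxc4 was called too (6.69). List-alone adjustment gave the same numbers. Under both scalings 683 genes were higher and 927 lower in hindbrain and cord, from 684 and 1227 of 6021 with control-probe scaling (shift −0.28) and 1193 and 1210 with quantile normalization.

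Astrocytes were compared between cortex and cerebellum. Regional transcription factors parted them: Lhx2 (13.36 ± 0.53 against 2.09, at least 164-fold, n = 4 against 3), Emx2 (10.20 ± 0.54, at least 18.4-fold) and Fezf2 (10.53 ± 0.26, at least 23.2-fold), all known from the developing forebrain, were higher in cortex. Pax3, a dorsal neural tube gene, was higher in cerebellum (2.37 against 10.55 ± 0.28, at least 23.4-fold). The AMPA receptor gene Gria4 (2.19 ± 0.21 against 13.20 ± 0.01, at least 147-fold) and the amino acid oxidase Dao (at least 41.5-fold) were also higher in cerebellar astrocytes. Of 18 astrocyte genes 3 were higher in cortex and 15 not called (median difference 0.29, adjusted p = 0.96). These were Aldh1l1 (11.65 ± 0.30 against 10.08 ± 0.02, 2.97-fold), the glutamate transporter Slc1a2 (14.16 ± 0.29 against 12.20 ± 0.17, 3.90-fold) and Sox9, whose call ended without cerebellar replicate 2 (0.98) or cortical replicate 4 (0.94) and under quantile normalization (0.82). Of 8 Bergmann glia genes 6 were higher in cerebellar astrocytes (median difference −1.45, adjusted p = 0.39), such as the growth factor gene Gdf10 (9.03 ± 0.62 against 14.20 ± 0.03, 36.1-fold) and Septin4 (10.89 ± 0.34 against 15.67 ± 0.05, 27.6-fold). Adjusted over the list alone, the counts were again 3 and 6. Of 4 blood and choroid plexus genes 3 were higher in cerebellar astrocytes (median difference −4.19, adjusted p = 0.39), and 9 of 12 cholesterol synthesis genes, such as Msmo1 (12.96 ± 0.38 against 10.70 ± 0.31), were higher in cortical ones (median difference 1.20, adjusted p = 0.56). When each tissue's unbound RNA was subtracted, Slc1a2 turned to −0.15, and 4 of the 6 Bergmann glia genes turned higher in cortex: Gdf10 to 1.13, Timp4 to 3.09, Cdc42ep4 to 1.89 and Ptch1 to 1.32. The both-scaling counts were 744 for cortex and 709 for cerebellum. Control-probe scaling gave 1000 and 715 of 5889, with a shift of 0.13. Quantile normalization turned the balance, with 805 and 1070.

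Bergmann glia, the radial glia of the cerebellar cortex, were compared with cerebellar astrocytes. Most genes of the Bergmann list did not part them: Septin4 (15.87 ± 0.17 against 15.67 ± 0.05, n = 3 each) and Gdf10 (14.80 ± 0.05 against 14.20 ± 0.03) were not called. Of 8 genes only Gli1, a hedgehog transcription factor, was higher in Bergmann glia (8.28 ± 0.49 against 6.51 ± 0.05, 3.40-fold; median difference 0.30, adjusted p = 0.91). Larger differences lay in genes of oligodendrocytes, higher in the Bergmann population, such as Mal (12.79 ± 0.20 against 7.59 ± 0.07, 36.7-fold), Mog (10.55 ± 0.37 against 5.17, at least 23.4-fold) and Opalin (10.79 ± 0.01 against 4.48, at least 27.6-fold). Genes of choroid plexus and meninges were higher in the astrocyte population, such as the potassium channel Kcnj13 (1.84 against 8.96 ± 0.71, at least 7.78-fold) and Ogn (at least 8.64-fold). Of 11 myelinating oligodendrocyte genes 8 were higher (median difference 4.55, adjusted p = 0.058 and 0.029 under quantile normalization) and of 3 blood and choroid plexus genes 3 lower in Bergmann glia (median difference −5.21, adjusted p = 0.011). Of 18 astrocyte genes 1 was lower, the intermediate filament gene Gfap (11.79 ± 0.30 against 13.39 ± 0.07, 3.04-fold), and 17 were not called (median difference 0.10, adjusted p = 0.91, with a median of 0.32 over all genes and a negative test). The Gfap call ended without Bergmann replicate 3 (−1.43). Counts adjusted over the list alone were the same for both planned lists. In all, 179 genes were higher in Bergmann glia and 236 in astrocytes under both scalings. Control-probe scaling gave 466 and 236 of 4341, with a shift of 0.43. Quantile normalization gave 243 and 537.

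The Olig2 line tags oligodendroglia of all stages and the Cmtm5 line mature oligodendrocytes, and their comparison in cortex asked which genes belong to the immature cells. Progenitor genes were higher in the mixed population: the growth factor receptor Pdgfra (13.90 ± 0.01 against 10.17 ± 0.02, 13.3-fold, n = 3 each) and the proteoglycan genes Cspg4 (10.53 ± 0.18 against 7.13 ± 0.38, 10.6-fold) and Vcan (10.06 ± 0.15 against 2.15 ± 0.15, at least 16.7-fold). The receptor gene Gpr17 (17.5-fold) and the cell-cycle gene Ccnd1 (34.2-fold) were higher too. Mature oligodendrocytes were higher for the myelin gene Mag (9.98 ± 0.07 against 12.11, 4.37-fold), the connexin Gjb1 (7.15 ± 0.02 against 9.48 ± 0.41, 5.03-fold) and the protease Klk6 (4.56 ± 0.01 against 9.89, at least 14.8-fold). Mbp, which encodes myelin basic protein, was not called (15.43 ± 0.01 against 15.83 ± 0.16). All 10 tested progenitor genes were higher in the mixed population (median difference 3.92, adjusted p = 0.069 and 5.8e-05 under quantile normalization). Of 16 myelinating genes 7 were higher in mature cells, 1 in mixed cells and 8 not called (median difference −0.67, adjusted p = 0.70). Among the 7, Cmtm5 (11.06 ± 0.02 against 12.21 ± 0.08) lost its call without mature replicate 3 (−1.11) or mixed replicate 1 (−1.14), and Mog without mature replicate 1 (−0.70), mixed replicate 1 (−0.95) or mixed replicate 2 (−1.05). The exception, Gjc3, ended without mature replicate 2 (0.53), mature replicate 3 (0.70) or mixed replicate 1 (0.67). Of 12 cholesterol synthesis genes 2 were higher in mature cells, 1 in mixed cells and 9 not called (median difference 0.01, adjusted p = 0.86, below the median of 0.83 over all genes, hence a negative test). Of 12 astrocyte genes 10 were higher in the mixed population (median difference 1.35, adjusted p = 0.86). Under both scalings the mixed population had 1629 genes higher and 455 lower. Control-probe scaling gave 2832 and 455 of 6520, with a shift of 0.59. Quantile normalization gave 1629 and 1201.

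In the cerebellum the same pair of lines gave Pdgfra at 13.46 ± 0.15 against 7.30 ± 0.33 (71.7-fold, n = 3 each) and Gpr17 at 13.39 ± 0.13 against 7.42 ± 0.19 (62.9-fold), both higher in mixed oligodendroglia. The complement-like gene C1ql1 (10.92 ± 0.01 against 2.30, at least 30.4-fold) and the signalling gene Bmp4 (10.89 ± 0.19, at least 29.7-fold) were higher there too. The homeobox gene Meox1 was at least 73.3-fold higher there (12.20 ± 0.29 against 2.39). The nuclear RNA Malat1 was higher in mature cells (8.06 ± 0.19 against 14.04 ± 1.10, 62.8-fold, difference −6.60 to −5.57 when 1 array is left out), and Mbp was not called (15.66 ± 0.11 against 15.60 ± 0.11). All 9 tested progenitor genes were higher in the mixed population (median difference 5.98, adjusted p = 0.015). Of 16 myelinating genes 2 were higher in mature cells, 1 in mixed cells and 13 not called (median difference −0.31, adjusted p = 0.55), and adjusted over the list alone only Gjc3 was called (8.60 ± 0.01 against 10.01 ± 0.42, 2.66-fold). The other two, Gjb1 and Fa2h, lost their call without any of several replicates, Gjb1 without mature replicate 3 (−0.49), mixed replicate 1 (−1.02) or mixed replicate 2 (−1.01) and Fa2h without mature replicate 2 (1.00), mixed replicate 1 (1.18) or mixed replicate 2 (1.19). Of 12 cholesterol synthesis genes 1 was called, the sterol cyclase Lss, higher in mixed cells (9.80 ± 0.11 against 7.90 ± 0.15, 3.73-fold; median difference 0.58, adjusted p = 0.64, below the median of 0.83 over all genes). Both scalings gave 1510 and 310 genes. Control-probe scaling gave 1901 and 322 of 4288, with a shift of 0.37. Quantile normalization gave 1772 and 695.

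Mature oligodendrocytes were then compared between cortex and cerebellum. Cortical cells were higher for Kalrn (13.82 ± 0.40 against 7.97 ± 1.72, 57.8-fold, n = 3 each), the chemokine Cx3cl1 (11.08 ± 0.22 against 6.63 ± 0.26, 21.9-fold) and the glypican Gpc5 (9.55 ± 0.68, at least 11.7-fold). Cerebellar cells were higher for Malat1 (7.78 ± 4.03 against 14.04 ± 1.10, 76.3-fold). Leaving out 1 array put the Malat1 difference at −8.50 to −4.62 and that of Kalrn at 4.86 to 6.44. Most genes of myelin were not called, among them Mbp (15.83 ± 0.16 against 15.60 ± 0.11) and Cmtm5 (12.21 ± 0.08 against 12.54 ± 0.63), and of 16 myelinating genes 2 were lower in cortex (median difference −0.36, adjusted p = 0.97). These were the connexin genes Gjc3 (7.04 ± 1.69 against 10.01 ± 0.42, 7.84-fold, difference −3.94 to −2.40 when 1 array is left out) and Gjb1, whose call ended without cerebellar replicate 3 (−0.75) or cortical replicate 2 (−1.09). When each tissue's unbound RNA was subtracted, Cmtm5 turned to 2.60, Gjb1 to 1.89, Mobp to 1.26 and Ugt8a to 1.12. Progenitor genes were higher in the cortical cells, 3 of 4 tested (median difference 2.35, adjusted p = 0.028), with Pdgfra at 10.17 ± 0.02 against 7.30 ± 0.33 (7.30-fold), Cspg4 at 7.13 ± 0.38 against 4.36 ± 0.29 and Gpr17 at 9.36 against 7.42 ± 0.19. Counts adjusted over the list alone were identical. Neuronal lists moved with the region without a called gene: the Purkinje list (median difference −6.53, adjusted p = 0.00014) and the granule list (median difference −8.08, adjusted p = 4.0e-05) were lower, and the cortical glutamatergic list higher in cortex (median difference 3.17, adjusted p = 0.028). Of these, 5, 4 and 4 members passed in limma, all of those tested, but were not higher in TRAP than in unbound RNA on the higher side. Under both scalings 225 genes were higher in cortex and 242 in cerebellum. Control-probe scaling gave 225 and 429 of 4324, with a shift of −0.28. Quantile normalization gave 713 and 428.

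**Figure D4:**
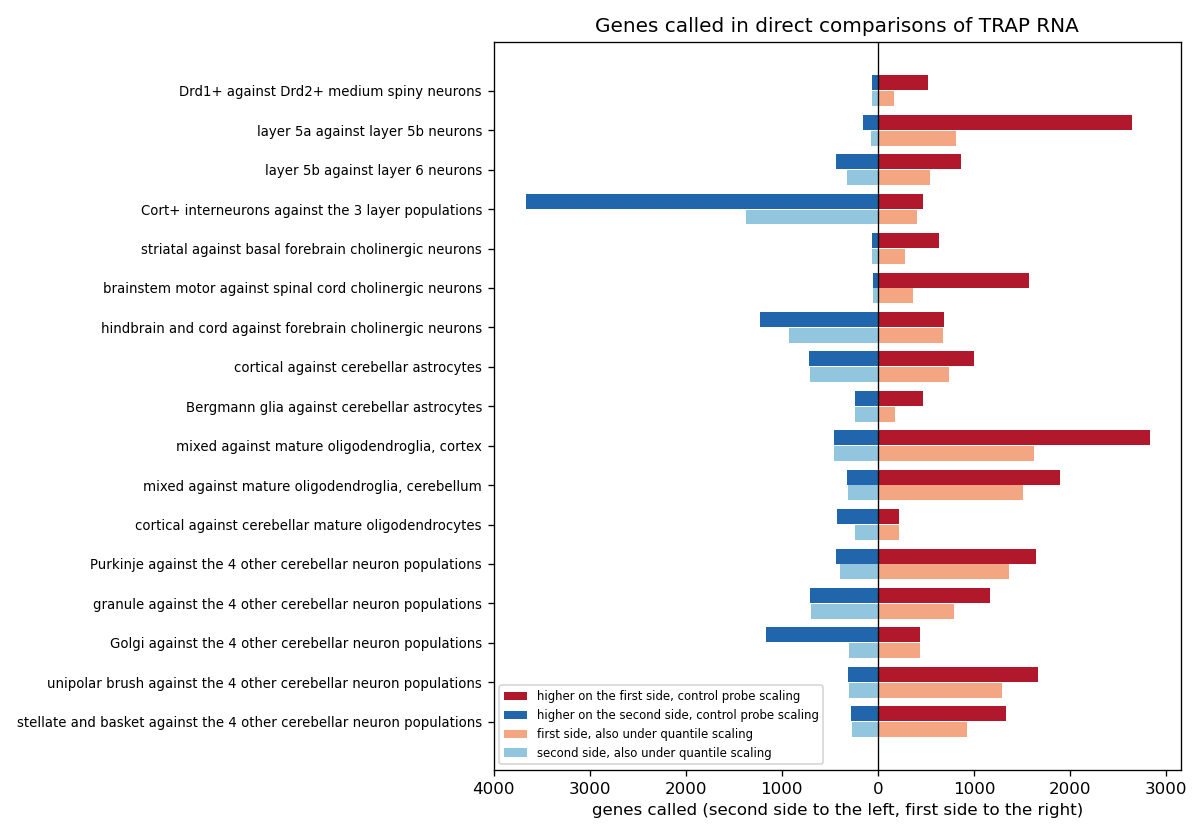
Number of genes called higher on each side of the 17 comparisons of populations, with control-probe scaling and under both this scaling and quantile normalization. With control-probe scaling the counts run from 225 to 2832 for the first-named side and from 50 to 3662 for the other.

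Each of the 5 cerebellar neuron populations was set against the mean of the other 4, to find the genes that set it apart. Purkinje neurons, the output neurons of the cerebellar cortex, were higher for Pcp2 (16.12 ± 0.17 against 10.69 ± 0.57, 43.0-fold, n = 6 against 12), the calcium buffer Calb1 (31.5-fold) and Car8 (16.27 ± 0.14 against 11.58 ± 0.44, 25.9-fold), with Calb1 not tested under quantile normalization. They were also higher for the phosphatase inhibitor Ppp1r17 (15.63 ± 0.19 against 9.13 ± 0.33, 90.4-fold), the glutamate transporter Slc1a6 (11.89 ± 0.17, at least 50.5-fold) and Foxp2 (10.52 ± 0.32 against 2.68 ± 0.0039, at least 22.9-fold). The growth factor Fgf7 (15.12 ± 0.19, at least 312-fold) and the serotonin receptor Htr1b (12.25 ± 0.38, at least 76.4-fold) were among the largest gains, and the connexin Gjd2 among the largest losses (2.26 ± 0.06 against 9.90 ± 0.21, at least 14.9-fold). All 10 tested genes of the Purkinje list were higher (median difference 5.27, adjusted p = 0.29 and 0.011 under quantile normalization), with the same 10 adjusted over the list alone. Of 7 granule genes 7 passed as lower in limma (median difference −2.54, adjusted p = 0.56) but were not called, because on average over the other populations they were not higher in TRAP than in unbound RNA. Both scalings gave 1370 genes higher and 394 lower. Control-probe scaling gave 1651 and 438 of 6658, with a shift of −0.06. Quantile normalization gave 1871 and 1145.

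Granule neurons, the small excitatory neurons of the cerebellar cortex, were higher for the transcription factor Neurod1 (14.80 ± 0.12 against 10.01 ± 0.28, 27.6-fold, n = 3 against 15) and the secreted synaptic organizers Cbln3 (14.72 ± 0.05 against 9.68 ± 0.33, 32.8-fold) and Cbln1 (14.65 ± 0.11 against 12.43 ± 0.30, 4.64-fold), the last 2 not tested under quantile normalization. The secretion gene Cadps2 (14.42 ± 0.05 against 9.32 ± 0.35, 34.2-fold) and Slc17a7 (8.85 ± 1.04 against 4.22 ± 0.01, at least 4.02-fold) were higher as well. The carbonic anhydrase Car4 (10.71 ± 0.40, at least 21.2-fold) and the zinc transporter Tmem163 (11.19 ± 0.47, at least 34.5-fold) were higher too, and Nrsn2 lower (at least 29.7-fold). All 7 tested granule genes were higher (median difference 4.63, adjusted p = 0.40 and 0.0097 under quantile normalization), adjusted over the list alone as well. Of 10 Purkinje genes 9 passed as lower in limma (median difference −2.72, adjusted p = 0.40) but were not called, because on average the other populations did not have them higher in TRAP than in unbound RNA. Genes called under both scalings were 792 higher and 697 lower. Control-probe scaling gave 1165 and 711, with a shift of 0.32. Quantile normalization gave 1415 and 1589.

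Golgi neurons, inhibitory interneurons of the granule layer, were higher for the glutamate receptor Grm2 (10.36 ± 0.02 against 3.96 ± 0.06, at least 13.4-fold, n = 3 against 15) and the glycine transporter Slc6a5 (10.97 ± 0.30 against 2.12, at least 31.4-fold). Higher were also Penk (14.28 ± 0.25 against 6.42 ± 0.14, at least 81.6-fold), Lgi2 (13.21 ± 0.17 against 8.79 ± 0.23, 21.4-fold) and Gad1 (14.61 ± 0.26 against 12.95 ± 0.34, 3.18-fold). Vwc2, which encodes a secreted protein, was higher as well (at least 193-fold), and the kinase Camk1 (at least 11.0-fold) and Wfs1 (at least 11.6-fold) were lower. All 7 Golgi genes were higher, also adjusted over the list alone (median difference 4.42, adjusted p = 0.0072), and 3 of 3 GABAergic genes (median difference 3.79, adjusted p = 0.040 and 0.32 under quantile normalization). Of 7 granule genes 6 passed as lower in limma (median difference −2.63, adjusted p = 0.80), without a call because of the same requirement. All genes lay −1.14 from the other populations at the median, and under both scalings 437 genes were higher and 298 lower. Control-probe scaling alone gave 437 and 1160, and quantile normalization 1721 and 917.

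Unipolar brush neurons, excitatory interneurons of the granule layer, were higher for Grp (14.89 ± 0.06 against 3.33 ± 0.06, at least 474-fold, n = 3 against 15), the T-box factor Eomes (12.90 ± 0.03 against 6.89 ± 0.39, at least 40.7-fold) and Sln (14.94 ± 0.04 against 5.42 ± 0.59, at least 246-fold). So were the glycine receptor gene Glra2 (12.57 ± 0.13 against 4.58 ± 0.16, at least 65.2-fold) and Slc17a7 (9.38 ± 0.03 against 4.08 ± 0.52, at least 6.35-fold). The calcium buffer Calb2 was not called (10.03 ± 0.26 against 9.90 ± 0.44). Samhd1 was lower (2.14 against 10.58 ± 0.28, at least 23.9-fold). Of 3 tested genes of their list 2 were higher and 1 not called (median difference 6.01, adjusted p = 0.28), and of 7 granule genes 2 were higher and 5 not called (median difference 1.07, adjusted p = 0.77), with the same counts adjusted over the list alone. Astrocyte genes were higher as well, 9 of 10 tested (median difference 5.76, adjusted p = 0.16 and 0.021 under quantile normalization), such as Slc1a3 (12.91 against 7.48 ± 0.19), and 7 of 7 Bergmann glia genes (median difference 4.42, adjusted p = 0.16 and 0.021 under quantile normalization), such as Gdf10 (13.35 ± 0.25 against 6.84 ± 0.27). Under both scalings 1297 genes were higher and 301 lower. Control-probe scaling gave 1666 and 311, with a shift of 0.36. Quantile normalization gave 1600 and 1100.

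Stellate and basket neurons, inhibitory interneurons of the molecular layer, were higher for Lypd6 (13.97 ± 0.03 against 4.40 ± 0.57, at least 250.5-fold, n = 3 against 15), Pvalb (15.29 ± 0.04 against 12.07 ± 0.42, 9.33-fold) and the receptor kinase Kit (12.91 ± 0.08 against 5.62 ± 0.21, at least 68.8-fold). Higher too were the sorting receptor Sorcs3 (at least 10.9-fold), Gad1 (14.89 ± 0.06 against 12.88 ± 0.36, 4.05-fold), the transcription factor Tfap2b (at least 24.9-fold) and the cannabinoid receptor Cnr1 (14.03 ± 0.06 against 11.03 ± 0.18, 8.02-fold). The adaptor gene Sla was among the largest gains (14.48 ± 0.10, at least 323-fold). All 9 genes of their list were higher, also adjusted over the list alone (median difference 4.98, adjusted p = 0.056 and 0.00077 under quantile normalization). Of 7 granule genes 5 had an unadjusted p under 0.05 in limma (median difference −0.27, adjusted p = 0.69), and 3 of them also passed the adjusted threshold and 2-fold, but were not higher in TRAP than in unbound RNA on the other side. Progenitor genes of oligodendroglia were higher too, 4 of 5 tested (median difference 4.94, adjusted p = 0.056 and 0.00077 under quantile normalization), such as Pdgfra (9.07 ± 0.12 against 2.24 ± 0.05) and Gpr17 (7.88 ± 0.38 against 2.04 ± 0.09), as were 3 of 4 myelinating oligodendrocyte genes (median difference 5.43, adjusted p = 0.16). Under both scalings 929 genes were higher and 273 lower. Control-probe scaling gave 1332 and 284, with a shift of 0.41. Quantile normalization gave 1278 and 908.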

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

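The tests on layers 5a and 5b, on Samhd1 and Cacng7 and on deep-layer neurons of the Drd1 line were chosen after the result was seen, and the other tests on the Drd1 line and the splits of the arrays before it.

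Cortical projection neuron genes were higher in Drd1 than in Drd2 TRAP RNA by a median of 2.35 (SD 1.51) over the 10 called members of both cortical lists (Foxp2 at 11.73, Ccn2 at 11.40), 4 of which also lay above the expression minimum in the Drd2 line. More cortex in the dissected tissue would raise these genes in unbound RNA about as much. There the lines differed by a median of 0.29 (SD 0.79), although 8 of 10 lay higher in the Drd1 line. Under quantile normalization they differed by −0.47, against 2.16 in TRAP RNA. Most of the genes lay under the expression minimum in the unbound RNA of both lines, such as Tbr1 (3.85 in the Drd1 and 3.63 in the Drd2 line). A difference may be hidden there, so for them this test cannot decide. Foxp2, Rprm and Sulf1 lay above the minimum in both and differed there by 0.47, 0.05 and 1.00, against 1.77, 1.20 and 1.70 in TRAP RNA. Carry-over of unbound RNA would leave the 10 genes no higher than in that RNA. They stood 1.85 above it at the median (10 of 10 higher, 9 under quantile normalization), but within the SD of 2.17 over the genes that the test had set as its bar, so carry-over stays open. Dropping the requirement of TRAP over unbound RNA calls the same 10 genes. Tagged ribosomes in deep-layer cortical neurons of this line may add to the pattern but stay open too: all 12 expressed layer 6 genes, called or not, stood 1.39 further above unbound RNA than 9 callosal genes (joint SE 0.70), just under 2 joint standard errors, and 1.52 under quantile normalization (0.74). A difference of the medium spiny neurons themselves was not tested and stays open.

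Microglia genes in layer 5a TRAP RNA stood 4.58 above layer 6 at the median (9 genes, with Ctss at 13.37 and C1qb at 12.43), and 4 of the 7 that were higher than in layer 5b were also expressed there, while vascular genes in layer 5b stood 2.11 above layer 6 (11 genes, with Cldn5 at 9.46 and Slco1a4 at 8.79). Carry-over of unbound RNA alone would leave these lists no higher than unbound cortex. They stood 3.11 above it in layer 5a (SE 0.55, quantile 2.27 with SE 0.57) and 3.14 in layer 5b (SE 0.62, quantile 2.75 with SE 0.75). Relative to all genes tested, the control-probe values were 1.80 and 2.45. The lists had been seen above unbound RNA before this test was chosen, and the SE takes their genes as independent. The values thus go against carry-over as the only source, but are no independent test of it. A lower share of neurons would raise 5 lists of other cell types. Against layer 6 all rose in layer 5a (spread 3.55, joint SE 0.91, microglia 4.58, progenitors 1.03), so it stays open there. In layer 5b not all did (spread 2.32, joint SE 0.87, vascular 2.11, progenitors −0.21). Tagged ribosomes in macrophages or vessel cells of these lines remain a candidate source and were not tested. No biological explanation was tested.

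Samhd1 and Cacng7 were both called higher in TRAP than in unbound RNA in 7 of 24 populations (8 under quantile normalization): cerebellar astrocytes, Bergmann glia and Cck+, Cort+, Golgi, granule and Purkinje neurons. RNA that binds in every purification would appear in all populations, so the 7 argue against it. A strain variant would act on unbound RNA too. Yet the mean of both genes stood 6.39 (Purkinje neurons) and 5.06 (Bergmann glia) above the same line's unbound RNA (5.66 and 6.19). Cck+ neurons stood 3.77 above their 1 unbound array, itself at 8.39 against 2.77 in that of the astrocyte line. Cerebellar astrocytes stood 7.04 above the highest of 3 cortical arrays of the same line, TRAP or unbound, which argues against a variant of that line that acts in cortex too. A strain variant stays open for Cck+ neurons and for Cort+, Golgi and granule neurons, which lack unbound arrays of their line. A gap of 7.23 within cortex, between Cck+ or Cort+ neurons and the highest of 4 other neuron populations, argues against a cortex-cerebellum difference. A shared preparation, probe specificity and a biological explanation stay open and untested.

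Of 37 tests for a sample far from the others of its group, 2 stood out, and chance gives about 1 in 20 groups. Purkinje TRAP replicate 2 had a mean of 4.58 over the myelinating oligodendrocyte list, against 4.27 to 4.33 in the other 5 arrays. The unbound array of the Pnoc line had 30.6% of its values at the minimum, against 32.0% to 32.3% in the other 8 cortical ones. The difference between mixed and mature oligodendroglia itself differed between cortex and cerebellum for 2481 of 7329 genes (2759 under quantile normalization, 2124 under both), with opposite signs for 1091, and Meox1 stood at 3.05 and 2.06 in cortex but 12.20 and 2.39 in cerebellum. The difference between cortex and cerebellum differed between astrocytes and mature oligodendrocytes for 3263 of 7037 genes (3050 under quantile normalization, 2455 under both), with opposite signs for 2397, and the receptor gene Grin2c stood at 10.76 and 4.36 in astrocytes but 3.22 and 9.41 in oligodendrocytes. Grin2c is also a member of the granule neuron list, which stood higher in cerebellar than in cortical mature oligodendrocytes (median −8.08, adjusted p = 4.0e-05). Among 9160 probe sets without a gene symbol, which no comparison used, a median of 140.5 per population were higher in TRAP than in unbound RNA (25 to 473).

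Other splits of the same arrays, each fitted on those arrays alone, gave as many calls in 1 split per result, the real one. For 9 comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real and the highest other counts were 610 and 0 for Drd1 against Drd2, 2783 and 0 for layer 5a against 5b, 1237 and 0 for layer 5b against 6, 737 and 0 for striatal against basal forebrain, 1603 and 0 for brainstem against cord, 724 and 0 for Bergmann glia. They were 3239 and 0 for mixed against mature cells in cortex, 2199 and 0 in cerebellum, and 546 and 0 for mature cells between regions. For the others the real split alone of 35 or 100 called as many, with 4140 and 3596 for Cort+ neurons, 1912 and 1257 for hindbrain and cord, 1697 and 466 for astrocytes (35 splits). A wrong split mixes populations whose own arrays are alike, which widens the spread within its groups. The splits therefore show that the true grouping called the most genes, and cannot exclude chance for the calls themselves. The cerebellar counts were 2093 and 544 for Purkinje, 1884 and 1241 for granule, 1600 and 421 for Golgi, 1985 and 947 for unipolar brush, and 1624 and 681 for stellate and basket neurons. Over the 24 populations the median was 1366.5, with 0 in the highest other split. Single populations gave more calls in a wrong split for Drd2 (1567, real 1310) and several times more for Pnoc+ neurons (1864, real 259). For layer 5b (3280, real 3401) and layer 5a (4754, real 6325) a wrong split also gave many calls. The cause was not tested.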

How the results depend on the processing

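The control-probe alternative by set of arrays, the requirement of both scalings, and the comparisons without layer 5a or without Golgi neurons were chosen after the data were seen. With eBayes without trend, the compared arrays alone, scaling by set of arrays, single BAC lines, without layer 5a, without Golgi neurons and with the replicate number as a block, each count stayed within 1.5 times its reported value. Leaving out any 1 array also kept every count within it, the widest ranges being 477 to 834 for striatal against basal forebrain neurons (698), 522 to 795 for mature oligodendrocytes (654) and 1081 to 1571 for layer 5b against 6 (1305), with 17 drivers throughout. Among single genes in comparisons, leaving out 1 array kept 6242 results, made 36 weaker and 20 stronger and reversed 0, and quantile normalization kept 556, with 9 weaker and 32 stronger. Of 38 list results chosen for a comparison beforehand, 31 stayed on their side of the threshold under quantile normalization and 24 with the preset correlation, and the other 7 and 14 became stronger. Among the other lists quantile normalization ended 1 of 7 in comparisons, GABAergic genes in Golgi neurons, and 1 of 11 over unbound RNA, the Golgi list in Golgi neurons, and the preset correlation ended 0. Weak signals limit these arrays: up to 41.6% of values stood at the minimum.

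The values that moved follow, with the reported count in brackets. Without further scaling the counts were 136 for Drd1 against Drd2 [592], 1769 for layer 5a against 5b [2801], 359 for striatal against basal forebrain [698], 2471 for brainstem against cord [1621], 1359 for Bergmann glia [702]. They were 4401 for mixed against mature cells in cerebellum [2223], 3051 for Golgi [1597] and 3777 for unipolar brush neurons [1977]. Drd1 in its own line over unbound RNA turned from 1.08 to −0.18. Quantile normalization gave 292 for Drd1 against Drd2, 1182 for layer 5a against 5b, 2325 for Cort+ neurons [4134], 1035 for brainstem against cord, 1141 for mature oligodendrocytes [654], 3004 for granule [1876] and 2638 for Golgi neurons. Genes called under both scalings were 232 for Drd1 against Drd2, 889 for layer 5a against 5b, 856 for layer 5b against 6, and 1777 for Cort+ neurons. They were 340 for striatal against basal forebrain, 413 for brainstem against cord, 415 for Bergmann glia, 2084 for mixed against mature cells in cortex [3287] and 735 for Golgi neurons, fewer by construction. For the scalings the cause was not tested.

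Without an expression filter more genes were tested, and the counts were 986 for Drd1 against Drd2, 2135 for layer 5b against 6, 1083 for striatal against basal forebrain, 1291 for Bergmann glia and 1124 for mature oligodendrocytes. With a minimum of 8 fewer were tested, giving 274, 725, 414, 390 and 405 in the same order. The mean of all probe sets gave 860 for layer 5b against 6 and turned Sc5d in cerebellar mixed against mature cells from −0.89 to 1.70, and the cause was not tested.

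Testing against 2-fold with treat is stricter by construction and gave 135 for Drd1 against Drd2, 852 for layer 5a against 5b, 245 for layer 5b against 6, 1809 for Cort+ neurons, 108 for striatal against basal forebrain, and 359 for brainstem against cord. It gave 1245 for hindbrain and cord against forebrain [1911], 799 for astrocytes [1715], 246 for Bergmann glia, 1802 for mixed against mature cells in cortex and 1313 in cerebellum. It gave 155 for mature oligodendrocytes, 1179 for granule, 982 for Golgi and 960 for stellate and basket neurons [1616], and a median of 780 over the 24 populations [1485.5].

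Without the requirement of TRAP over unbound RNA more genes were tested, with counts of 1226 for striatal against basal forebrain, 3431 for brainstem against cord, 3675 for hindbrain and cord against forebrain, 2840 for astrocytes, and 1895 for Bergmann glia. The counts were 3909 for mixed against mature cells in cerebellum, 2643 for mature oligodendrocytes, 4960 for Purkinje [2089], 4969 for granule, 6349 for Golgi, 3870 for unipolar brush and 3492 for stellate and basket neurons. Requiring 1.5-fold left fewer genes, with 843 for brainstem against cord, 406 for mature oligodendrocytes, 984 for granule and 807 for Golgi neurons. With unbound arrays of the same line alone 16 populations remained, of which 10 had their driver called [17 of 19 tested], against 11 of the same 16 with all unbound arrays.

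Subtracting each tissue's unbound RNA gave 1740 genes for striatal against basal forebrain, 974 for brainstem against cord, 3899 for astrocytes and 2328 for mature oligodendrocytes, and it reversed genes, for which the cause was not tested. These were Zic4 (2.52), Zic1 (1.61) and Rasd2 (−1.34) between striatum and basal forebrain, and Chodl (2.51) and Mmp9 (1.03) between brainstem and cord. Between astrocytes they were Slc1a2 (−0.15), Slc1a3 (2.07), Aqp4 (1.83), Slc4a4 (2.41), S100b (2.29), Atp1b2 (2.89), Gdf10 (1.13), Hopx (3.22), Timp4 (3.09), Cdc42ep4 (1.89) and Ptch1 (1.32), and between mature oligodendrocytes Cmtm5 (2.60), Mobp (1.26), Gjb1 (1.89) and Ugt8a (1.12).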

Other observations

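Several gene families fixed beforehand were tested in each population but belong to no comparison, and their values are medians of TRAP minus unbound RNA relative to all genes tested, with adjusted p-values that use an estimated correlation. Potassium channel genes, which shape the firing of neurons, were lowest in cortical astrocytes (−3.97, 34 of 44 genes lower, adjusted p = 0.31). Glutamate receptor genes stood highest in layer 6 neurons (0.64, 13 of 18 higher, adjusted p = 1.00) and lowest in cortical astrocytes (−4.82, 12 of 16 lower, adjusted p = 0.27), and of 4 acetylcholine receptor genes 4 were higher in layer 6 neurons (1.28, adjusted p = 1.00). Genes of GABA receptors were lowest in Purkinje neurons (−3.88, 6 of 8 lower, adjusted p = 0.78), and serotonin receptor genes stood highest in Pnoc+ neurons (0.67, 1 of 6 higher, adjusted p = 0.55). Cholesterol synthesis genes, which supply the lipid of myelin, stood highest in cerebellar mature oligodendrocytes (2.00, 5 of 12 higher, adjusted p = 0.89). Immediate early genes, which respond to activity and to handling of tissue, were lowest in Purkinje neurons (−4.17, 7 of 7 lower, adjusted p = 0.65).

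Housekeeping families were tested as well. Genes of cytosolic ribosomal proteins ranged from −0.85 in Drd1 neurons (3 of 41 lower, adjusted p = 0.76) to 1.85 in Golgi neurons (4 of 42 higher, adjusted p = 0.68), and oxidative phosphorylation genes from −0.48 in layer 5a (1 of 78 lower, adjusted p = 0.95) to 2.07 in Golgi neurons (2 of 78 higher, adjusted p = 0.68). Hox genes were tested in brainstem and spinal cord only, at −0.76 (4 of 9 lower, adjusted p = 0.87) and −0.39 (1 of 18 higher, adjusted p = 0.90). With 3 clusters of populations, the unipolar brush, stellate and basket, granule and Purkinje neurons formed a group of their own, and with 4 the oligodendroglia parted from the astrocytes and Bergmann glia.

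Where TRAP and unbound arrays share a line and number, a fit with the replicate as a block could be had for 9 populations. It gave a median of 1489 genes higher in TRAP RNA, against 1484 for the same populations without the block, and 4 drivers called with and without it. In Drd1 neurons the block raised the genes called higher from 2705 to 3158, and in brainstem motor neurons from 934 to 974. For the comparisons of populations a block on the replicate number gave 578 genes for Drd1 against Drd2, 2721 for layer 5a against 5b and 1045 for layer 5b against 6, and no count moved by more than 1.5 times.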
